A study of Homo sapiens with 16 samples.

How the data were processed

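Messenger RNA was sequenced from DU145 cells, an established human prostate cancer line, in 16 libraries. The libraries fall into 4 groups of 4 replicates: control, lactate, I-BET762, and lactate together with I-BET762. I-BET762 is a small molecule that blocks the bromodomains of BET proteins, which bind acetylated histones. The labels call the replicates independent and give no dose and no duration for either treatment. In the 4 samples given both treatments, the cell line field carries line numbers that differ from the DU145 of their titles, and the titles were followed. Per the labels' protocols, 800 ng of RNA went into each library, the libraries were made with a strand-marking kit after selection of polyadenylated RNA, and reads were single ends of 75 bp.

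The authors deposited raw read counts per Ensembl gene, with 1 column per library, for 64792 gene identifiers. Per the submitters' processing notes, STAR 2.6.1c and DESeq were among the tools and GRCh38.p12 and hg38 were the builds. The counting program, its strand setting and the annotation release are not given in the sources used here. Counts of genes with near-identical copies, such as histone and ribosomal protein genes, and counts of overlapping or antisense genes are therefore uncertain. BRD2 had at most 3 counts and SLC16A1 at most 1 count in any library, so neither was tested, and these counts were not read as absence of the transcripts. Symbols came from a table of gene names and from GENCODE release 29 on GRCh38, which together named 42465 of the identifiers; coordinates are those of that release. No sample column went unused.

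Genes were kept by edgeR's filterByExpr at a minimum count of 10 and a minimum total of 15, which left 14690 genes. These held at least 99.82% of the counts of every library. Library sizes were scaled by TMM, and the 4 group means were fitted in 1 quasi-likelihood model in edgeR 4.0.16 (R 4.3.3) over all 16 libraries, with 12 residual degrees of freedom and a common biological coefficient of variation of 0.183. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold, and all tests were two-sided. The 5 comparisons of groups and the interaction of the treatments were contrasts of this model. Expression levels are edgeR's CPM values on TMM-scaled library sizes, given as mean ± SD over the 4 replicates, and fold changes are on the log2 scale with their standard errors (SE).

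The 30 gene lists were written, and the model, the tests and the rule for naming genes fixed, before the data were examined. Of 682 list entries, 680 were matched to an identifier. The 29 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, and p was adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of changed members are also given adjusted over the list alone. Genes were named by 3 parts of the rule. The first part gave HEXIM1, SERPINI1, MYC, FOSL1, BRD2, BRD3, SLC16A1, SLC16A3, LDHA, LDHB, PLIN2, ACLY, CPT1A, PDK4 and ANGPTL4 whatever their result, besides an item that is not reported here. The second gave the 6 largest rises and 6 largest falls (4 and 4 in the comparisons of both treatments with I-BET762 and with control, and for the interaction) among changed genes with a mean of at least 5 CPM and, except for the interaction, no overlap between the libraries of the 2 groups. The third gave up to 4 members with the smallest p of each list described. HEXIM1, a gene known to rise under BET inhibitors, served as a check of the inhibitor labels.

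The share of the lactate response kept under the inhibitor was the slope through the origin of the log2 fold changes of both treatments against I-BET762 on those of lactate against control. Genes were chosen on the libraries of 2 of the replicate numbers and the x values taken from the other 2. The mirror slope was made likewise. For the overlap of the responses to lactate and to I-BET762, which share the control libraries, unchanged groups were simulated together with controls that they share. GC content and exon length, known for 99.37% of the tested genes, were related to each gene's deviation from its mean over the 16 libraries by Spearman's correlation across genes within each library.

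The test was run on counts simulated for the 14690 genes of lactate against control. It recovered 17 of 100 genes changed 1.5-fold and 63 of 100 genes changed 2-fold, and 3 of its 83 calls (3.6%) were false. The simulated counts gave every group the same spread per gene and drew each gene separately. They held no outlying library and no trend on GC content or exon length. These shares are therefore not the error rates of the real calls. Alternatives were RLE size factors, total counts alone, no filter on low counts, a mean of at least 5 CPM, replicate number as a block, DESeq2 1.42.0, limma-voom, the groups compared fitted alone, a fold threshold of 2, and each library left out in turn. Corrections for GC content and exon length (loess span 0.3), library quality weights, and fits without doubtful libraries were added after the data had been seen.

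The libraries held 10711859 to 17173584 counts. A count of 0 allowed up to 3 counts, or 0.175 to 0.28 CPM depending on the library, a limit that covers counting error alone. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom ran from 2.06, for I-BET762 replicates 3 and 4, to 164.61, for lactate replicates 1 and 3. Nothing in the labels gives a sequencing batch or date.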

Results

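Expression was measured by RNA sequencing in DU145 prostate cancer cells kept as control, given lactate, given the BET bromodomain inhibitor I-BET762, or given both. Each group had 4 libraries. The study's title places it in work on lactate, lipid metabolism and chromatin in prostate cancer. Total counts per library were 13300345 to 15867437 in the control group and 10711859 to 17173584 with lactate. They were 13741178 to 16847884 with I-BET762 and 14358751 to 14641934 with both. The lowest total belonged to lactate replicate 1. In the model of all 16 libraries, most of the expression differences followed lactate, and fewer followed the inhibitor. That model shares the spread of each gene among the groups, and the largest differences between replicates were among lactate libraries. Fitted on the compared groups alone, lactate against control gave 889 genes and I-BET762 against control 496. Both treatments against I-BET762 then gave 2535 genes, and both against lactate 2. The sizes of the counts in different comparisons therefore depend on the model.

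HEXIM1, a brake on transcription elongation whose gene is known to rise under BET inhibitors, was examined first because it checks the inhibitor labels. The gene (ENSG00000186834) lies on chromosome 17 at 45148502 to 45152101, plus strand, in GRCh38. It stood at 75.7, 70.0 and 77.4 CPM in the libraries labelled control replicates 1, 3 and 4, and at 135.1 CPM in the library labelled control replicate 2. In the libraries labelled I-BET762 replicates 1, 3 and 4 it stood at 148.8, 113.3 and 113.8 CPM, and in the library labelled I-BET762 replicate 2 at 89.6 CPM. The 4 lactate libraries held 69.6 to 86.0 CPM and the 4 libraries given both treatments 115.1 to 156.9 CPM. The check therefore went against the labels of the libraries labelled control replicate 2 and I-BET762 replicate 2. Their labels were kept in every comparison, and directions drawn from the control and I-BET762 groups rest on these labels.

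**Figure D1:**
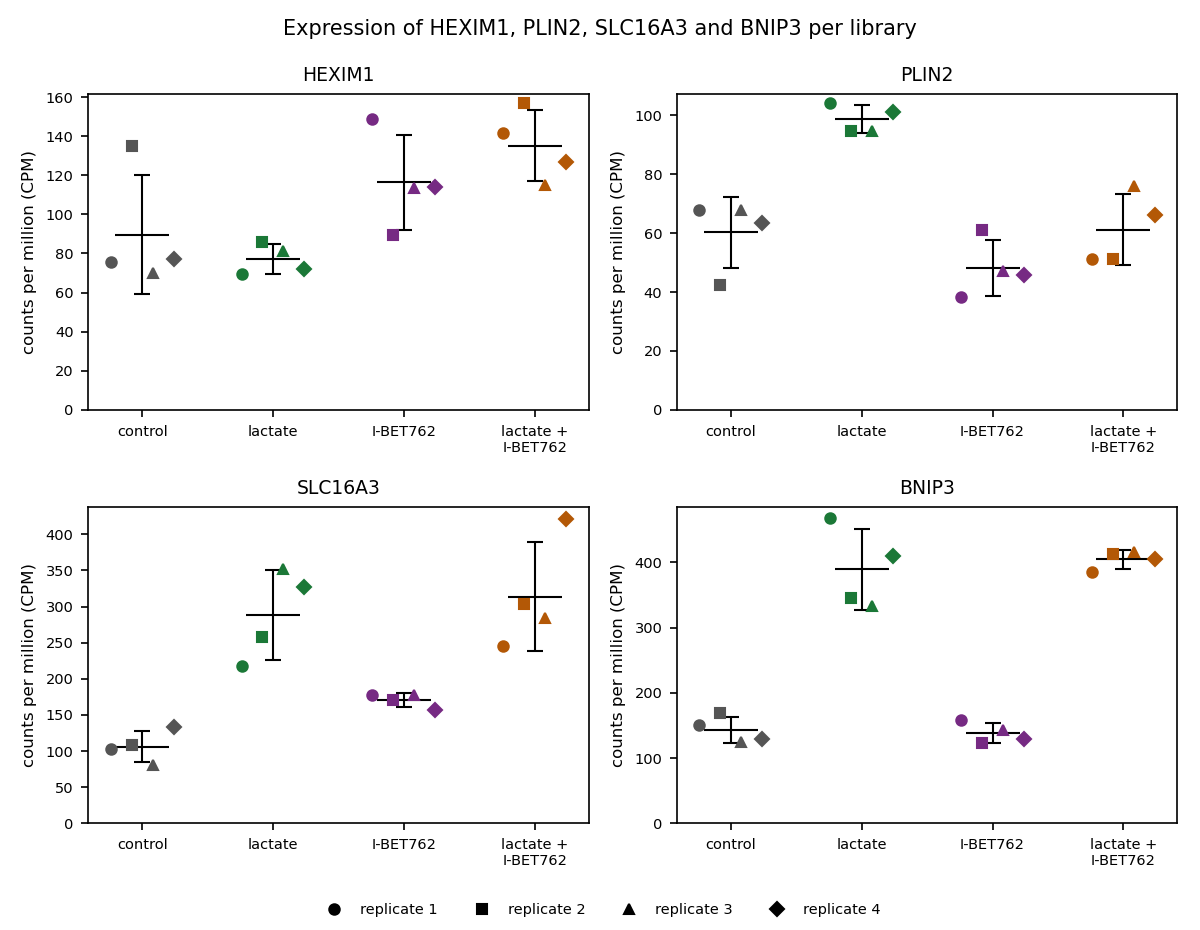
Expression of HEXIM1, PLIN2, SLC16A3 and BNIP3 in CPM (vertical axes, from 0) in each of the 16 libraries by group, with a marker per replicate number and bars for mean ± SD (n = 4). HEXIM1 was 135.1 CPM in the library labelled control replicate 2 and 89.6 CPM in the library labelled I-BET762 replicate 2, whereas BNIP3 and SLC16A3 were higher in every lactate library than in every control library.

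The first comparison asked what lactate alone did to the cells. Under the labels as given, lactate changed 3486 of the 14690 genes tested, with 2003 higher and 1483 lower. Genes of the hypoxia response, the programme that cells switch on at low oxygen, rose together. Of 21 tested members 13 were higher and 0 lower (also 13 and 0 adjusted over the list alone), with a median log2 fold change of 0.66 (camera adjusted p = 4.4e-08, and adjusted p = 0.0087 with an estimated correlation). BNIP3, a mitophagy receptor (ENSG00000176171, chromosome 10, 131966455 to 131982013), rose from 143.3 ± 20.1 to 389.1 ± 62.5 CPM (n = 4 each; log2 fold change 1.44, SE 0.13, edgeR adjusted p = 1.08e-05). NDRG1, the pyruvate dehydrogenase kinase PDK1 and the collagen hydroxylase P4HA1 rose by 1.29, 1.5 and 0.92 on the log2 scale. Glycolysis genes rose in the same comparison, with 8 of 20 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.0012, but adjusted p = 0.48 with an estimated correlation). The phosphofructokinase regulator PFKFB4, the enolase ENO2 and the phosphoglycerate kinase PGK1 rose by 1.45 (SE 0.12), 1.14 (SE 0.15) and 0.72 (SE 0.10). SLC16A3, which encodes the lactate exporter MCT4 (ENSG00000141526, chromosome 17, 82228397 to 82261129), rose from 106.2 ± 21.7 to 288.4 ± 61.8 CPM (log2 fold change 1.44, SE 0.18, edgeR adjusted p = 0.00019). LDHA had a log2 fold change of 0.23 (adjusted p = 0.147) and LDHB of 0.78 (SE 0.38, adjusted p = 0.136). LDHB stood at -0.08 without lactate replicate 1. The list of lactate and pyruvate transport and entry, with 6 of 19 members higher and 0 lower (6 and 1 adjusted over the list alone), did not pass the list test (adjusted p = 0.055).

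Lipid genes were spread over several groups under lactate. Cholesterol synthesis and uptake rose, with 10 of 25 members higher and 0 lower, also adjusted over the list alone (median log2 fold change 0.22, camera adjusted p = 0.0035, but adjusted p = 0.11 with an estimated correlation). Its leading members were the sterol reductase TM7SF2 (1.42, SE 0.16, edgeR adjusted p = 8.82e-05), MVD (1.70, SE 0.24) and MVK (0.71, SE 0.12), both of the mevalonate pathway. Targets of the peroxisome proliferator-activated receptors rose as well, with 7 of 16 higher and 0 lower by either count (camera adjusted p = 0.013, but adjusted p = 0.11 with an estimated correlation). Among them, HILPDA, an inhibitor of lipid droplet breakdown, rose by 1.59 and the uncoupling protein UCP2 by 1.49. Lactate replicate 1 stood apart for both. HILPDA was 66.6 CPM there against 24.1, 23.2 and 32.7 CPM in the other lactate libraries, and UCP2 36.4 against 79.5, 78.0 and 79.9 CPM. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 1.30, from 10.1 ± 2.1 to 24.9 ± 2.9 CPM. PLIN2, a lipid droplet coat protein (ENSG00000147872, chromosome 9, 19108375 to 19149290), rose from 60.4 ± 12.1 to 98.7 ± 4.8 CPM (log2 fold change 0.71, SE 0.17, edgeR adjusted p = 0.00798). The list of lipid droplet and triglyceride storage held 6 higher and 2 lower members of 22 by either count and did not move as a whole (adjusted p = 0.68). Its median log2 fold change was -0.04 and its mean 0.18, the direction of its test. Its members AGPAT2 and PLIN3 rose by 1.02 and 0.72, but after correction for GC content they stood at 0.25 (adjusted p = 0.135) and 0.42 (adjusted p = 0.0668). Fatty acid synthesis and activation held 4 higher and 1 lower of 23 (adjusted p = 0.82), with MLXIPL at 1.10 and ACSS2 at 0.64. Fatty acid oxidation held 5 higher and 0 lower of 26 (adjusted p = 0.2), with ACADS at 1.56 and CPT1C at 1.24. Fatty acid uptake and binding held 2 higher and 0 lower of 11 (1 and 0 adjusted over the list alone; adjusted p = 0.2), with SLC27A1 at 1.53. The citrate lyase ACLY (0.02, adjusted p = 0.938), CPT1A (-0.23, adjusted p = 0.117) and PDK4 (0.46, adjusted p = 0.258) did not pass the test. CPT1A and PDK4 are members of the list of peroxisome proliferator-activated receptor targets, so its rise did not extend to them.

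Genes of dividing cells fell under lactate. In the list "cell cycle, mitosis", 11 of 24 members were lower and 1 higher by either count (camera adjusted p = 0.00092, but adjusted p = 0.33 with an estimated correlation). Among them were the checkpoint kinases BUB1 (-0.62, SE 0.10) and TTK (-0.51, SE 0.10) and the motor KIF11 (-0.58, SE 0.11). DNA replication genes fell, with 6 of 24 lower and 0 higher by either count (adjusted p = 0.03, but adjusted p = 0.71 with an estimated correlation). The helicase subunit MCM3 was among them (-0.60). The list MYC and ribosome biogenesis fell, with 9 of 26 lower and 1 higher by either count (adjusted p = 0.013, but adjusted p = 0.42 with an estimated correlation). UTP20 (-0.93) and NOLC1 (-0.47) led it, while MYC itself stood at -0.13 (adjusted p = 0.406). The oxidative stress response fell, with 6 of 19 lower and 1 higher (adjusted p = 0.03, but adjusted p = 0.42 with an estimated correlation). The cystine transporter SLC7A11 (-0.91) and the glutathione reductase GSR (-0.55) fell with it. Single libraries carried some of these list calls. DNA replication stood at adjusted p = 0.057, 0.16, 0.15 and 0.073 without control replicate 1, control replicate 2, lactate replicate 2 and lactate replicate 3. MYC and ribosome biogenesis stood at 0.076 without control replicate 2, and oxidative stress response at 0.066, 0.15 and 0.095 without control replicate 4, lactate replicate 2 and lactate replicate 3.

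The interferon response rose under lactate, with 6 of 18 members higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.016, but adjusted p = 0.69 with an estimated correlation). ISG15, a ubiquitin-like antiviral protein, rose by 2.21 (SE 0.35, edgeR adjusted p = 0.000842). The interferon response was lower in the library labelled control replicate 2 than in the other controls, and its list call was lost without that library (adjusted p = 0.11) and without lactate replicate 3 (adjusted p = 0.073). Cytosolic ribosomal proteins (11 of 30 higher, 0 lower; 15 and 0 adjusted over the list alone) and the nuclear-encoded respiratory chain (6 of 36 higher, 1 lower; 5 and 1 adjusted over the list alone) passed the list test at adjusted p = 0.00068 and 0.024. They stood at adjusted p = 0.71 and 0.83 with an estimated correlation. Both calls were lost without lactate replicate 1 (adjusted p = 0.1 and 0.83), and that of the nuclear-encoded respiratory chain also without lactate replicate 4 (adjusted p = 0.058). Lactate replicate 1 stood apart. It had a mean of cytosolic ribosomal proteins 1.23 above the control mean on the log2 scale against -0.02, 0.01 and 0.47 in the other lactate libraries. Spearman's rho of expression on exon length, across genes, was -0.40 in lactate replicate 1 and -0.42 in lactate replicate 4, against 0.24 and 0.10 in lactate replicates 2 and 3. AP-1 and immediate early genes did not pass as a list (5 higher, adjusted p = 0.18), with JUN at 0.74 and JUNB at 1.29. After correction for GC content and exon length JUNB stood at 0.41 (adjusted p = 0.0848). NF-kB and inflammatory cytokines did not pass either (3 higher and 1 lower, adjusted p = 0.12), with CXCL1 at 1.06 and CCL20 at 1.40. Amino acid and unfolded protein stress held 1 higher and 4 lower (adjusted p = 0.44). Histone genes (3 higher and 1 lower, adjusted p = 0.6), the histone acetylation machinery (3 and 1, adjusted p = 0.89) and the tricarboxylic acid cycle (2 and 2, adjusted p = 0.89) did not pass. Ion and pH handling (1 and 3, adjusted p = 0.5) and mitochondrially encoded transcripts (0 and 2, adjusted p = 0.18) did not pass either. Genes reported to rise under BET inhibitors (5 and 0, adjusted p = 0.53), those reported to fall (1 and 0, adjusted p = 0.6) and epithelial-mesenchymal transition (1 and 0, adjusted p = 0.68) likewise stayed below the threshold. Among markers of other cells, fibroblast markers held 2 higher of 5 tested (adjusted p = 0.057) and luminal prostate markers 1 of 6 (adjusted p = 0.82). Of the leukocyte markers 2 were tested and 1 was higher.

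Among genes with a mean of at least 5 CPM and no overlap between the groups, the largest rises under lactate were those of SPAG4 (ENSG00000061656, chromosome 20, 35615892 to 35621049; 2.56, SE 0.18, from 5.3 ± 0.5 to 31.6 ± 8.4 CPM, edgeR adjusted p = 7.3e-07) and NUDT18 (2.23). They were followed by ISG15 (2.21), the tight-junction protein CLDN3 (2.18), ELMO3 (2.17) and CCDC85B (2.12). The largest falls were those of the orphan nuclear receptor NR4A3 (ENSG00000119508, chromosome 9, 99821855 to 99866891; -1.34, SE 0.18), the nuclear envelope protein SYNE1 (-1.24), the amino acid transporters SLC1A4 (-1.13) and SLC7A6 (-1.05), the ion channel TRPV1 (-1.06) and IL18BP (-1.03). Among the lactate libraries, each of these falling genes was lowest in replicates 1 and 4, which had the lowest rho on exon length. SYNE1 stood at 22.9, 66.9, 38.0 and 23.1 CPM in lactate replicates 1 to 4, and UTP20 at 49.7, 87.0, 70.0 and 46.7 CPM. Across genes, Spearman's rho of the lactate log2 fold change on exon length was -0.34. In the fit of the lactate and control libraries alone, TRPV1, IL18BP and NOLC1 stood at adjusted p = 0.0586, 0.0742 and 0.0558. The BET gene BRD3 (0.13) did not pass. Nor did HEXIM1 (-0.21, adjusted p = 0.421), SERPINI1 (-0.03) or FOSL1 (-0.48, adjusted p = 0.0896). HEXIM1 stood at 0.05 without the library labelled control replicate 2. Of the tested genes, 2941 showed no overlap between the lactate and control libraries, against the 2.857% of genes that chance gives for 4 against 4. The trend of expression on GC content differed between the groups. Across genes, Spearman's rho averaged 0.20 ± 0.16 in the lactate libraries and -0.41 ± 0.11 in the control libraries (exact permutation p = 0.02857, the smallest that 4 against 4 allows; genes are not independent replicates). The genes higher under lactate had a median GC content of 59.8%, against 49% of all tested genes and 43.3% of the genes lower. After correction for GC content 1872 genes were called, 950 higher and 922 lower. After correction for GC content and exon length there were 1032 higher and 1091 lower. In the fit of these 2 groups alone 889 were called, of which the share higher was 80.9% against 57.5% in the model of all groups. Without control replicate 3 the count was 1849, and without lactate replicate 4 it was 2097.

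**Figure D2:**
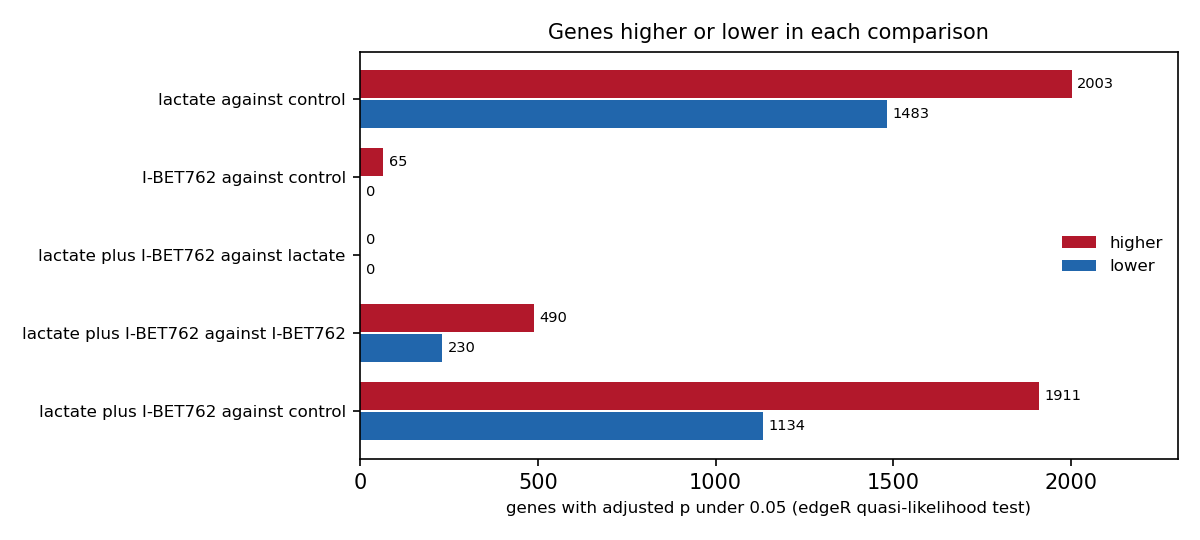
Number of genes higher or lower in each comparison of 2 groups (horizontal axis, genes with adjusted p under 0.05 in edgeR's quasi-likelihood test, 4 libraries per group). Lactate against control gave 2003 higher and 1483 lower genes, I-BET762 against control 65 and 0, both treatments against lactate 0 and 0, both against I-BET762 490 and 230, and both against control 1911 and 1134. The counts come from the model of all 4 groups. Fits of the compared groups alone called 889 genes for lactate against control and 496 for I-BET762 against control. They called 2535 for both treatments against I-BET762.

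The second comparison asked what the inhibitor did alone. I-BET762 raised 65 genes and lowered 0 against control, under the labels as given. At a mean of at least 5 CPM and without overlap, the largest rises were those of SCAND1 (ENSG00000171222, chromosome 20, 35953617 to 35959472; 1.99, SE 0.37, from 4.8 ± 1.9 to 19.2 ± 6.9 CPM), CCDC85B (1.88), CLDN3 (1.79), MCRIP1 (1.65), BBLN (1.59) and the membrane metalloprotease MMP17 (1.54). Each had an edgeR adjusted p of 0.0473, the smallest of this comparison. Histone genes rose as a list, with 1 of 21 members higher over all genes and 7 adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 8.1e-07, but adjusted p = 0.52 with an estimated correlation). The linker histone H1-10 rose by 1.06, from 52.0 ± 14.6 to 108.5 ± 11.2 CPM. H2AX (1.03, adjusted p = 0.0727) and H2BC4 (0.77, adjusted p = 0.0791) passed only adjusted over the list alone (0.0106 each). The list BET inhibitor genes reported to rise was higher too, with 0 of 15 members changed over all genes and 3 adjusted over the list alone (median 0.38, camera adjusted p = 0.0043, but adjusted p = 0.66 with an estimated correlation). Its call was lost without I-BET762 replicate 4 (adjusted p = 0.083). Its 3 members past the test over the list alone were H2BC4, ZCCHC24 (0.41) and H2BC5 (0.71). The list "cell cycle, mitosis" fell, with 0 of 24 members changed by either count (median -0.17, camera adjusted p = 6e-04, but adjusted p = 0.66 with an estimated correlation). Its smallest p was that of CCNA2 (-0.27, adjusted p = 0.244). In this comparison fry called 0 lists in either direction.

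HEXIM1 had a log2 fold change of 0.38 in this comparison (SE 0.19, adjusted p = 0.486), SERPINI1 of 0.16, MYC of 0.11 (adjusted p = 0.841), FOSL1 of -0.09 and BRD3 of 0.21. Genes reported to fall under BET inhibitors did not pass as a list (0 of 9 changed, adjusted p = 0.57). Without the libraries labelled control replicate 2 and I-BET762 replicate 2, HEXIM1 stood at 0.75 (adjusted p = 0.0524). Of metabolic genes, the short-chain acyl-CoA dehydrogenase ACADS rose by 1.03, the MCT chaperone BSG by 0.78, from 410.7 ± 76.6 to 702.8 ± 84.9 CPM, and OSGIN1 by 1.22. Hypoxia response (0 of 21 changed, adjusted p = 0.5), glycolysis (0 of 20 changed and 1 adjusted over the list alone, adjusted p = 0.57) and lipid droplet and triglyceride storage (0 of 22, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.76) did not pass. The same held for SLC16A3 (0.69, adjusted p = 0.0753), ANGPTL4 (0.72, adjusted p = 0.0688), PLIN2 (-0.33, adjusted p = 0.499), PDK4 (-0.56, adjusted p = 0.57), LDHA (-0.08), LDHB (0.04), ACLY (-0.04) and CPT1A (0.05). At an unadjusted p under 0.05 there were 1682 genes, and 1582 showed no overlap between the groups, against 2.857% by chance. DESeq2 called 526 genes and limma-voom 0. The 65 genes had a median GC content of 65%. The correlation of expression with GC content averaged 0.03 ± 0.17 in the I-BET762 libraries against -0.41 ± 0.11 in the controls (exact permutation p = 0.02857). After correction for GC content 0 genes were called, and with both libraries labelled replicate 2 left out, 9 (5 higher and 4 lower), of which 1 was among the 65. The count was 0 without control replicate 1, 2 or 3, and without lactate replicate 2, 3 or 4. It was also 0 without I-BET762 replicate 1, 2 or 3, or replicate 1, 2 or 4 of both treatments. It was 279 without control replicate 4, 649 without lactate replicate 1, 105 without I-BET762 replicate 4 and 220 without replicate 3 of both treatments.

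**Figure D3:**
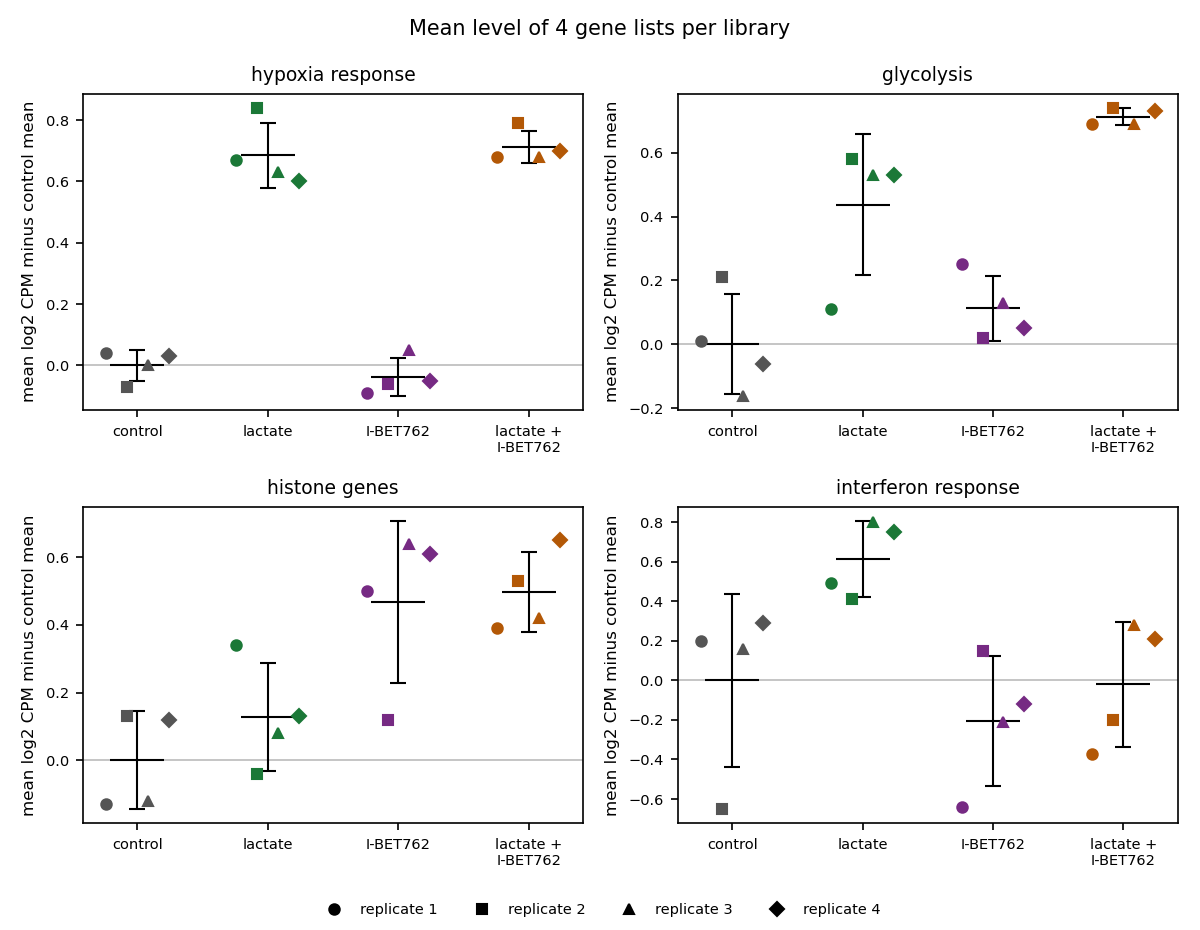
Mean log2 CPM of 4 gene lists, minus the control mean (vertical axes), in each of the 16 libraries by group, with a marker per replicate number and bars for mean ± SD (n = 4). Hypoxia response was higher in every library given lactate than in every library without it, and the interferon response stood at -0.65 in the library labelled control replicate 2 against 0.16 to 0.29 in the other controls.

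The third comparison asked what the inhibitor did to cells that had lactate. No single gene passed the test over all genes. edgeR called 0 genes, with 2294 at an unadjusted p under 0.05 and a smallest adjusted p of 0.221, while DESeq2 called 80 and limma-voom 0. HEXIM1 was at 135.1 ± 18.1 CPM with both treatments and 77.2 ± 7.6 CPM with lactate, without overlap (log2 fold change 0.81, SE 0.19, adjusted p = 0.00277 over the list alone). Genes reported to rise under BET inhibitors rose as a list, with 0 of 15 members higher over all genes and 6 adjusted over the list alone (median 0.34, camera adjusted p = 0.00034, but adjusted p = 0.42 with an estimated correlation). Histone genes rose likewise (0 and 6 of 21, median 0.48, camera adjusted p = 0.00047, but adjusted p = 0.42 with an estimated correlation). The core histones H2BC4, H2BC5 and H2BC21 stood at 0.90, 1.01 and 0.90, with adjusted p = 0.00565, 0.00565 and 0.0126 over the histone list alone. The interferon response fell as a list, with 0 of 18 lower over all genes and 7 adjusted over the list alone (median -0.58, camera adjusted p = 1.3e-05, but adjusted p = 0.42 with an estimated correlation). IFI44 (ENSG00000137965, chromosome 1, 78649796 to 78664078) stood at -2.02 (SE 0.45), MX2 at -1.09 and the exonuclease ISG20 at -1.26, from 32.9 ± 14.4 to 13.7 ± 3.0 CPM. Levels of the first 2 were low, at 4.9 to 10.5 CPM for IFI44 and 2.5 to 3.4 CPM for MX2 in the lactate libraries. NF-kB and inflammatory cytokines fell likewise, with 7 of 20 lower and 2 higher adjusted over the list alone (median -0.36, camera adjusted p = 0.0051, but adjusted p = 0.42 with an estimated correlation). The chemokines CXCL1 (-1.07) and CCL20 (-1.05) and the growth factor CSF2 (-1.26) were among them. Without lactate replicate 2, histone genes stood at adjusted p = 0.051 and NF-kB and inflammatory cytokines at 0.059. For both treatments against lactate fry called 0 lists, so none of the list changes here and in the next paragraph passed it.

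Mitochondrially encoded transcripts rose with the inhibitor in lactate-treated cells, with 0 of 13 higher over all genes and 8 adjusted over the list alone (median 0.60, camera adjusted p = 1.5e-05, but adjusted p = 0.42 with an estimated correlation). Among them were MT-CYB (0.65), MT-CO3 (0.36) and MT-ND2 (0.62). The list mean relative to control was -0.52, 0.00, -0.20 and -0.53 in lactate replicates 1 to 4, and 0.49, 0.37, -0.07 and 0.00 in those of both treatments. The lowest were lactate replicates 1 and 4, where rho of expression on exon length was -0.40 and -0.42, and replicates 3 and 4 of both treatments stood no higher, to 2 decimals, than lactate replicate 2. Glycolysis rose as a list with 0 of 20 members past either test (median 0.22, camera adjusted p = 0.00025, but adjusted p = 0.54 with an estimated correlation). Its member SLC2A1, a glucose transporter, stood at 0.44. Amino acid and unfolded protein stress fell with 0 of 21 past either test (median -0.27, camera adjusted p = 0.00091, but adjusted p = 0.57 with an estimated correlation). SHMT2 stood at -0.33 and TRIB3 at -0.63. Without lactate replicate 1, glycolysis and amino acid and unfolded protein stress stood at adjusted p = 0.0035 and 0.029. The list "cell cycle, mitosis" fell (0 and 1 of 24 lower, adjusted p = 0.027, but adjusted p = 0.63 with an estimated correlation). The call was lost at adjusted p = 0.051, 0.098, 0.24 and 0.1 without lactate replicate 2, lactate replicate 3, and replicates 2 and 4 of both treatments. Cytosolic ribosomal proteins (median -0.35, adjusted p = 0.00019) and the nuclear-encoded respiratory chain (-0.34, adjusted p = 0.0048) were lower, at adjusted p = 0.68 for both with an estimated correlation. Without lactate replicate 1 their direction turned (adjusted p = 0.9 and 0.59). Among lipid genes, PLIN2 stood at -0.69 (SE 0.17, 98.7 ± 4.8 against 61.2 ± 12.2 CPM), the lipases PNPLA3 at -0.65 and PNPLA2 at 0.88, each at adjusted p = 0.00566 over the list alone. Lipid droplet and triglyceride storage did not move as a list (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.59). The pentose phosphate enzyme PGD stood at 0.49 (adjusted p = 0.0239 over the list alone). Its list, the oxidative stress response, held 3 higher and 0 lower adjusted over the list alone (adjusted p = 0.34). MYC (0.12, adjusted p = 0.577), FOSL1 (-0.07), BRD3 (0.01) and SLC16A3 (0.12) did not pass. The same held for LDHA (0.23), LDHB (-0.89, adjusted p = 0.296, but -0.03 without lactate replicate 1), ACLY (0.31), CPT1A (0.07), PDK4 (-0.55), ANGPTL4 (-0.10) and SERPINI1 (0.27). No overlap between the groups was seen for 1117 genes, against 2.857% by chance. The correlation of expression with GC content did not separate them (0.29 ± 0.17 against 0.20 ± 0.16, exact permutation p = 0.4571). With the libraries labelled control replicate 2 and I-BET762 replicate 2 left out, the model called 60 genes, HEXIM1, PLIN2 and IFI44 among them at adjusted p = 0.0134, 0.0334 and 0.00943. With lactate replicate 1 also left out it called 123.

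The fourth comparison asked what lactate did to cells under the inhibitor. Lactate raised 490 genes and lowered 230 there, under the labels as given. Hypoxia response genes rose again, with 12 of 21 higher and 0 lower (18 and 0 adjusted over the list alone; median 0.76, camera adjusted p = 1.9e-18, and adjusted p = 0.00019 with an estimated correlation). BNIP3 went from 138.5 ± 15.6 to 404.5 ± 14.2 CPM (log2 fold change 1.55, SE 0.13, edgeR adjusted p = 4.89e-06), and P4HA1, PDK1 and the collagen cross-linking enzyme LOX rose by 1.10, 1.60 and 1.62. Glycolysis genes rose, with 10 of 20 higher and 1 lower (14 and 1 adjusted over the list alone; camera adjusted p = 2.2e-11, but adjusted p = 0.097 with an estimated correlation). Among them were PFKFB4 (1.58), PGK1 (0.96), ENO2 (1.42) and the hexokinase HK2 (1.59). Cholesterol synthesis and uptake rose, with 4 of 25 higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 3.7e-05, and adjusted p = 0.028 with an estimated correlation). TM7SF2 (1.08) and NSDHL (0.43) rose with it. Targets of the peroxisome proliferator-activated receptors rose, with 4 of 16 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.0023, and adjusted p = 0.034 with an estimated correlation). UCP2 (1.68) and TXNIP (2.85, SE 0.49) led them. ACSS2 rose by 0.89, SLC27A1 by 1.31, SLC16A3 by 0.88 (edgeR adjusted p = 0.00992) and LDHA by 0.54 (adjusted p = 0.0119, and 0.0536 without I-BET762 replicate 4).

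Amino acid and unfolded protein stress fell with lactate under the inhibitor, with 7 of 21 lower and 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 2.6e-06, but adjusted p = 0.18 with an estimated correlation). Among them were SLC7A11 (-1.05), MTHFD2 (-0.64), the serine synthesis enzyme PSAT1 (-0.82, from 950.8 ± 80.8 to 538.0 ± 27.9 CPM) and CHAC1 (-1.02). The oxidative stress response fell, with 4 of 19 lower and 0 higher (7 and 1 adjusted over the list alone; adjusted p = 0.00017, but adjusted p = 0.097 with an estimated correlation). GSR fell by 0.51. The list "cell cycle, mitosis" (1 of 24 lower, 3 adjusted over the list alone; adjusted p = 7.7e-06) and the list MYC and ribosome biogenesis (1 of 26 lower, 5 adjusted over the list alone; adjusted p = 0.00011) fell, at adjusted p = 0.12 and 0.14 with an estimated correlation. DNA replication fell with 1 of 24 lower (adjusted p = 0.0019, but adjusted p = 0.49 with an estimated correlation, and 0.06 without I-BET762 replicate 1). Fatty acid oxidation rose with 3 of 26 higher (adjusted p = 0.032, but adjusted p = 0.43 with an estimated correlation). That call was lost at adjusted p = 0.06, 0.084, 0.084 and 0.051 without I-BET762 replicate 1, I-BET762 replicate 2, and replicates 3 and 4 of both treatments. Lactate and pyruvate transport and entry (4 of 19 higher, 5 adjusted over the list alone, adjusted p = 0.076), fatty acid synthesis and activation (2 of 23 higher, 3 adjusted over the list alone, adjusted p = 0.3) and lipid droplet and triglyceride storage (1 of 22 higher, 1 higher and 2 lower adjusted over the list alone, adjusted p = 0.91) did not pass. Among genes with a mean of at least 5 CPM and no overlap, the largest changes were SPAG4 (1.86, SE 0.17), UCP2, PPP1R3G (1.67) and BAIAP3 (1.67) upward, and NR4A2 (-1.42), NR4A3 (-1.21), SLC1A4 (-1.18) and RASD1 (-1.16, adjusted p = 0.0184) downward. RASD1 lost its call at adjusted p = 0.0624 and 0.0585 without I-BET762 replicates 3 and 4, and at 0.0545, 0.0576 and 0.0552 without replicates 1, 2 and 3 of both treatments. PLIN2 (0.35, adjusted p = 0.264), ACLY (0.36, adjusted p = 0.257), ANGPTL4 (0.48, adjusted p = 0.128), HEXIM1 (0.22) and FOSL1 (-0.46) did not pass. Nor did MYC (-0.11), BRD3 (-0.07), SERPINI1 (0.08), LDHB (-0.15), CPT1A (-0.21) or PDK4 (0.47). No overlap was seen for 3310 genes, against 2.857% by chance. The correlation of expression with GC content averaged 0.29 ± 0.17 with both treatments and 0.03 ± 0.17 with I-BET762 (exact permutation p = 0.1143). The count was 1681 without lactate replicate 1, 434, 355 and 310 without I-BET762 replicates 2, 3 and 4, and 376, 390 and 283 without replicates 2, 3 and 4 of both treatments. It was 468 with the libraries labelled control replicate 2 and I-BET762 replicate 2 left out, and 2535 in the fit of these 2 groups alone. The latter held 1294 higher and 1241 lower (51% higher), and correction for GC content left 440 higher and 366 lower.

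The fifth comparison set both treatments against control. Together they raised 1911 genes and lowered 1134, under the labels as given. Hypoxia response rose with 15 of 21 higher and 0 lower (17 and 1 adjusted over the list alone; camera adjusted p = 2.7e-10, and adjusted p = 0.0031 with an estimated correlation). Glycolysis rose with 15 of 20 higher and 1 lower (16 and 1 adjusted over the list alone; adjusted p = 2.5e-08, but adjusted p = 0.21 with an estimated correlation). The list "cell cycle, mitosis" fell, with 16 of 24 lower and 0 higher (17 adjusted over the list alone; adjusted p = 4.5e-08, but adjusted p = 0.091 with an estimated correlation). Histone genes (8 of 21 higher, 10 adjusted over the list alone, adjusted p = 0.003) and genes reported to rise under BET inhibitors (7 of 15 higher by either count, adjusted p = 9e-04) rose, at adjusted p = 0.38 and 0.25 with an estimated correlation. Cholesterol synthesis and uptake rose with 7 of 25 higher (8 adjusted over the list alone; adjusted p = 0.00038, but adjusted p = 0.058 with an estimated correlation). HEXIM1 rose by 0.59 (SE 0.19, edgeR adjusted p = 0.0347) and SLC16A3 by 1.56 (SE 0.18). LDHA rose by 0.46, from 1316.2 ± 131.9 to 1810.0 ± 98.3 CPM, and ANGPTL4 by 1.20. PLIN2 was at 61.2 ± 12.2 CPM against 60.4 ± 12.1 CPM in control (log2 fold change 0.02, adjusted p = 0.952). HEXIM1 lost its call at adjusted p = 0.102, 0.124 and 0.0842 without control replicates 1, 3 and 4, and at 0.0747, 0.106 and 0.0618 without replicates 1, 2 and 4 of both treatments. Of genes at a mean of at least 5 CPM without overlap, BAIAP3 (ENSG00000007516, chromosome 16, 1333601 to 1349441; 2.90), CLDN3 (2.6), CCDC85B (2.52) and RHPN1 (2.35) rose most. NR4A2 (-1.44), SYNE1 (-1.20), SLC7A11 (-1.18) and SCEL (-1.16) fell most, with SCEL at adjusted p = 0.0624 without control replicate 3.

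Smaller list changes in that comparison were falls of amino acid and unfolded protein stress (6 of 21 lower by either count, adjusted p = 0.0041), DNA replication (7 of 24 lower, 8 adjusted over the list alone, adjusted p = 0.0062) and the list MYC and ribosome biogenesis (7 of 26 lower and 1 higher, 9 and 1 adjusted over the list alone, adjusted p = 0.014). They stood at adjusted p = 0.49, 0.53 and 0.38 with an estimated correlation. Fatty acid oxidation (6 of 26 higher, adjusted p = 0.025) and targets of the peroxisome proliferator-activated receptors (5 of 16 higher, adjusted p = 0.036) rose, at adjusted p = 0.4 and 0.15 with an estimated correlation. DNA replication and the list MYC and ribosome biogenesis stood at adjusted p = 0.1 and 0.14 without the library labelled control replicate 2. The list of peroxisome proliferator-activated receptor targets stood at 0.057, 0.056 and 0.073 without control replicate 2, control replicate 4 and replicate 3 of both treatments, and fatty acid oxidation at 0.073 without the last. Lipid droplet and triglyceride storage (4 higher and 2 lower, adjusted p = 0.87), lactate and pyruvate transport and entry (7 and 1, adjusted p = 0.15), MYC (-0.01) and FOSL1 (-0.55, adjusted p = 0.0655) did not pass. No overlap was seen for 4590 genes, against 2.857% by chance. The correlation of expression with GC content averaged 0.29 ± 0.17 against -0.41 ± 0.11 (exact permutation p = 0.02857), and 1487 genes were called after correction for GC content. The count was 1708 without control replicate 3, 4645 without lactate replicate 1, and 1950 and 1810 without replicates 2 and 4 of both treatments.

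Whether the inhibitor's effect differed with lactate was tested by the interaction itself. No gene passed. edgeR called 0 genes, with 894 at an unadjusted p under 0.05 and a smallest adjusted p of 0.7, and DESeq2 and limma-voom called 0. ANGPTL4 (-0.82), SLC16A3 (-0.56), PLIN2 (-0.36) and HEXIM1 (0.43) each had an adjusted p of 0.7. As lists, mitochondrially encoded transcripts (adjusted p = 0.00032) and glycolysis (0.024) shifted upward. Amino acid and unfolded protein stress (0.00043), cytosolic ribosomal proteins (0.00043), the nuclear-encoded respiratory chain (0.00096) and interferon response (0.03) shifted downward, with 0 members past the test over all genes. Each stood at adjusted p = 0.81 with an estimated correlation. Without lactate replicate 1, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain and glycolysis stood at adjusted p = 0.73, 0.69 and 0.37. Glycolysis was also lost without control replicate 2 (0.26), lactate replicate 3 (0.057) and I-BET762 replicate 4 (0.07). Interferon response was lost without control replicate 2 (0.45), lactate replicates 3 (0.26) and 4 (0.062), I-BET762 replicates 2 (0.12), 3 (0.055) and 4 (0.1), and replicates 1 (0.19) and 2 (0.13) of both treatments.

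The slope of the lactate response under the inhibitor on that without it was 0.60 over 2863 genes chosen on replicates 3 and 4, and 88.8% of these genes had the same sign. Its bootstrap range, 0.57 to 0.63, was over genes and left out the variation between libraries. Replicates 1 and 2 alone called 0 genes and gave no slope. In simulated data a full response gave 0.90 by the same route, and 0.96 with the noise of the x values subtracted, against 0.73 in the real data. The x values came from replicates 1 and 2, among them lactate replicate 1 and the library labelled control replicate 2. Without lactate replicate 1 the slope over these genes was 0.74, and 0.92 with noise subtracted. Without the libraries labelled control replicate 2 and I-BET762 replicate 2 it was 0.62 and 0.90, and without all 3 it was 0.73 and 0.84. In these 3 settings the x values rested on 1 lactate library, on 1 control library and on 1 of each, in that order. The higher slopes there are therefore weak support for a full response. Other noise-subtracted slopes were lower. Without lactate replicate 1 it was 0.61 over 206 genes chosen on replicates 1 and 2. It was 0.63 and 0.67 with replicates 1 and 4 set against 2 and 3, and 0.67 at a mean of at least 5 CPM. A reduced response was therefore neither established nor excluded. The mirror slope, for the inhibitor's response with lactate, was 0.18 over 17 genes (range -1.38 to 2.48). In the same 3 settings it was 0.65 (-1.03 to 2.81), 0.78 (0.67 to 0.93) and 0.79 (0.72 to 0.91) over these genes. These ranges too were over genes and left out the variation between libraries. In the last 2 settings the x values rested on 1 control and 1 I-BET762 library, so the mirror slope gave no usable bound. Fold changes under lactate and under I-BET762, which share the controls, had a covariance of 0.0764 across genes (jackknife SE 0.0446) and Pearson's r of 0.43. Simulated unchanged groups that shared simulated controls gave a covariance of 0.0315 and r of 0.501. With the controls split so that none was shared, the covariance was 0.0508 (0.0369 to 0.0791 over the splits) and r was 0.25. Of the genes called, 55 were higher in both comparisons, against 8.9 for independent lists and 0 in the simulation, and 5.2 on average with split controls, where 1 of 6 splits gave 31 and the other 5 gave 0; 0 were lower in both. CCDC85B and CLDN3 rose in both. The simulation drew each gene separately and held no trend on GC content. The real log2 fold changes followed GC content in both comparisons (Spearman's rho 0.44 with lactate and 0.54 with I-BET762). A response shared by the treatments was therefore not established.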

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

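The patterns below, the choice of their genes, and all tests of causes except those of exon length and read number in lactate replicate 1 were chosen only after the result was seen. The labels were taken as given throughout, and every value rests on 4 libraries per group.

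The genes that respond to the inhibitor set the libraries labelled control replicate 2 and I-BET762 replicate 2 against their groups. A score of 50 genes higher and 50 genes lower with the inhibitor, ranked only on the libraries given lactate, was 1.35 in the library labelled control replicate 2 and -0.36, -0.50 and -0.49 in the other controls, and -0.36 in the library labelled I-BET762 replicate 2 against 1.53, 1.07 and 1.10 in the others. An exchange of the labels of these 2 libraries might account for this, since the gap between the groups would then be 1.43 (within-group SD 0.16) against -1.71 for these 2 libraries as labelled. A bias of base composition or length is less likely, as the gap stayed at 1.38 (SD 0.15) after correction for GC content and exon length, and an equal mixture of the samples is unlikely, as the library labelled control replicate 2 lay at 1.07 of the way to the inhibitor (SD 0.11) where an equal mixture would lie midway. Other values kept both libraries with their labelled groups, such as rho of expression on GC content (-0.37 in the library labelled control replicate 2, others -0.56 to -0.30; 0.17 in the library labelled I-BET762 replicate 2, others -0.19 to 0.16) and SLC16A3 (108.3 and 170.1 CPM), so an exchange and cultures that responded differently both stay open.

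The calls of the inhibitor alone, and part of those of lactate and of both treatments against control, moved with GC content. The 65 genes higher with I-BET762 had a median log2 fold change of 1.06 (median SE 0.22) and 0.43 (SE 0.14) after correction for GC content; 65 of 65 kept their direction and 0 stayed called, so a technical bias and a real rise of GC-rich genes could each account for them. For lactate, 1872 genes were called after the correction, 1410 of the 3486 among them. The trend that was removed therefore does not account for those 1410 calls. The other splits of the 8 libraries called at most 1 gene after the same correction. They mix lactate and control libraries, so they cannot tell bias left after the correction from an effect of lactate. Genes higher with lactate had a median of 0.88 before and 0.54 after the correction, and genes lower -0.50 and -0.40. For both treatments against control the higher genes had a median of 0.86 before and 0.43 after it, and 665 of 1911 higher and 488 of 1134 lower genes stayed called.

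Cytosolic ribosomal proteins stood 1.08 higher in lactate replicate 1 than in the other lactate libraries (SD of those 0.28). After correction for GC content and exon length the difference was 1.01 (SD 0.22), and for exon length alone 1.00 (SD 0.23). A trend on this length therefore does not account for it. The length joins all annotated exons of a gene and is not that of the transcript present, so a loss of long transcripts stays open. Lactate replicates 1 and 4, with the lowest rho on exon length (-0.40 and -0.42), had the highest list means of the lactate libraries (1.23 and 0.47). Thinning another library to the same total moved the value by -0.00025, but the abundance of these genes fixed that outcome beforehand, so the number of reads was left untested. The mean of 5 fibroblast markers was lower in lactate replicate 1 than in the lowest other lactate library (difference -0.23). This argues only weakly against RNA of fibroblasts. COL5A1 and ACTA2 had few counts there (0.3 and 1.0 CPM), and S100A4 stood at 118.6 CPM against 40.1, 29.2 and 47.0 CPM. The list mean of lactate replicate 1 also lay 0.34 above the control mean. Handling of that culture or library might be the cause, which counts alone cannot test.

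Chance was weighed by exchanging libraries between the groups compared. For lactate against control, 1 of 35 splits (the real one) called as many genes (3486; highest other 1267, with control replicate 4 and lactate replicate 2 exchanged), so chance is unlikely. For I-BET762 against control it was 2 of 35 (65; highest other 104, of which 31 higher and 73 lower), so the share alone does not exclude chance. That other split exchanges the libraries labelled control replicate 2 and I-BET762 replicate 2, the exchange weighed above, and the remaining 33 splits called at most 1 gene, so it does not speak for chance either. For both treatments against lactate it was 35 of 35 (0; highest other 0), and for the interaction 100 of 100 drawn (0; highest other 269). With a real count of 0 every split calls as many, so these counts say nothing about chance. For both treatments against I-BET762 it was 1 of 35 (720; highest other 0) and against control 1 of 35 (3045; highest other 0), so chance is unlikely for both.

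Of 544 groups checked for a library far from its 3 replicates, 26 (4.779%) held one, about the 1 in 20 that chance gives. The mitochondrial share was 2.88% in control replicate 4 (others 3.47 to 3.59), and rho of expression on exon length was 0.03 there (0.24 to 0.27). List means relative to control were -0.22 for genes reported to fall under BET inhibitors in I-BET762 replicate 4 (others -0.14 to -0.13) and -0.32 for "cell cycle, mitosis" in lactate replicate 2 (-0.27). They were 0.16 for cytosolic ribosomal proteins in the library labelled I-BET762 replicate 2 (0.03 to 0.04), -0.29 for epithelial-mesenchymal transition in I-BET762 replicate 1 (-0.10 to -0.07) and 0.16 for fibroblast markers in the library labelled I-BET762 replicate 2 (-0.07). Glycolysis stood at 0.11 in lactate replicate 1 (0.53 to 0.58), hypoxia response at 0.79 in replicate 2 of both treatments (0.68 to 0.70) and interferon response at -0.65 in the library labelled control replicate 2 (0.16 to 0.29).

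Single genes stood apart, in CPM, as follows. HEXIM1 was 135 in the library labelled control replicate 2 (others 70 to 77.4), FOXM1 191 in control replicate 4 (177 to 180) and HILPDA 11 in control replicate 3 (12.3 to 12.5). In lactate replicate 1, UCP2 was 36.4 (78 to 79.9), ACSS2 227 (317 to 331), H2AX 46.9 (26.2 to 26.5) and PGD 120 (166 to 175). In I-BET762 replicate 1, IL18BP was 11.3 (12.6 to 12.7), PGK1 608 (518 to 532) and H2AX 60.8 (34.6 to 37.7). In the library labelled I-BET762 replicate 2, H2BC5 was 15.3 (36 to 39.7), SHMT2 390 (323 to 334), TRIB3 156 (103 to 107) and PGD 193 (261 to 267). With both treatments, LDHB was 74.9 in replicate 1 (69.7 to 70.4) and H2BC4 14.2 in replicate 3 (17.5 to 18).

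In the interaction, 6 lists passed the test without any gene doing so: amino acid and unfolded protein stress (adjusted p = 0.00043), cytosolic ribosomal proteins (0.00043), glycolysis (0.024), interferon response (0.03), mitochondrially encoded transcripts (0.00032) and nuclear-encoded respiratory chain (0.00096). Each stood at adjusted p = 0.81 with an estimated correlation, fry called 0 lists, and 3 of the 6 calls were kept without lactate replicate 1.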

How the results depend on the processing

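The corrections, the quality weights and the fits without doubtful libraries were chosen only after the result was seen. Where a value below moved, the cause was not tested, apart from settings that by construction test fewer or more genes (the filters), fewer libraries, or a narrower claim (the fold threshold). Named genes kept direction and side of the threshold in 2780 comparisons with 1 library left out, lost a call in 170 and gained one in 15. In 43 they changed direction without being called in either fit. For gene lists 2717 kept their side of the threshold, with uncalled lists that changed direction counted among them. A call was lost in 45 and gained in 20, and 2 with a call in at least 1 of the fits turned direction.

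Lactate against control gave 3486 genes, and 889 in the fit of its groups alone, 1872 after correction for GC content, 2123 after correction for GC content and exon length, and 852 at a fold threshold of 2. With 1 library left out the count ran from 1849 (control replicate 3) to 4932 (lactate replicate 2).

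I-BET762 against control gave 65 genes: 0 with total counts alone, 492 without a filter, 133 at a mean of at least 5 CPM, 206 with replicate number as a block, 526 with DESeq2, 0 with limma-voom, 1488 with quality weights, 496 in the fit of its groups alone, 0 after either correction and 41 at a fold threshold of 2. Without the libraries labelled control replicate 2 and I-BET762 replicate 2 it gave 9 (5 higher and 4 lower), and 977 (740 higher and 237 lower) without lactate replicate 1 as well. With 1 library left out it gave 0 to 649.

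Both treatments against lactate gave 0 genes: 197 without a filter, 80 with DESeq2, 107 with quality weights, 2 in the fit of its groups alone, 60 without the libraries labelled replicate 2 and 123 without lactate replicate 1 as well. With any 1 library left out it gave 0.

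Both treatments against I-BET762 gave 720 genes: 1212 with DESeq2, 4539 with quality weights, 2535 in the fit of its groups alone, 1124 after correction for GC content and exon length, 468 without the libraries labelled replicate 2, 1466 without lactate replicate 1 as well, 236 at a fold threshold of 2, and 283 to 1681 with 1 library left out.

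Both treatments against control gave 3045 genes: 5778 with quality weights, 4709 in the fit of its groups alone, 1487 and 1895 after the corrections, 4809 without the libraries labelled replicate 2 and lactate replicate 1, 880 at a fold threshold of 2, and 1708 to 4645 with 1 library left out. The interaction gave 0 genes and 3 without a filter.

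Camera made 51 list calls at the preset correlation and 5 with an estimated correlation. With fry there were 37, of which 26 were among the 51. None of the 37 came from I-BET762 against control, both treatments against lactate or the interaction. Calls of named genes numbered 102, and 73 to 126 in other settings. The lactate effect kept under the inhibitor was 0.60, 0.73 with noise subtracted, and 0.73 over 25 genes with replicates 1 and 3 set against 2 and 4. With replicates 1 and 4 set against 2 and 3 it was 0.55 over 2681 genes chosen on the former and 0.61 over 644 chosen on the latter. Without lactate replicate 1, replicates 1 and 2 chose 206 genes, with a slope of 0.59, and replicates 3 and 4 chose 2863, with 0.74 (mean 0.66). It was 0.62 without the libraries labelled replicate 2 and 0.73 without lactate replicate 1 as well. The mirror slope was 0.18, and -1.37 at a mean of at least 5 CPM. It was 0.46 without lactate replicate 1 (0.27 over 615 genes and 0.65 over 17), 0.78 without the libraries labelled replicate 2 and 0.79 without lactate replicate 1 as well.

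Without lactate replicate 1, cytosolic ribosomal proteins (adjusted p = 0.9) and the nuclear-encoded respiratory chain (0.59) turned direction in both treatments against lactate. With other libraries left out their adjusted p was as low as 3.8e-07 and 1.5e-05. With the libraries labelled replicate 2 also left out they stood at 0.9 and 0.55, and in the interaction 5 of 6 list calls were lost: cytosolic ribosomal proteins (0.47) and glycolysis (0.89) turned direction, and amino acid and unfolded protein stress (0.39), the nuclear-encoded respiratory chain (0.47) and interferon response (0.47) kept theirs.

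Replicate numbers were not used as pairs in the main model. Of 24 pairs of libraries with the same number, 16 correlated above 0.1 (-0.26 to 0.42), and 7 of 16 libraries matched best with their own number. The lowest value was that of the libraries labelled control replicate 2 and I-BET762 replicate 2. The mean was 0.17 against -0.06 for other pairs. Values were centred within groups, which forces these means to opposite signs, so the second adds nothing to the first. Libraries with the same number may therefore share some variation, which the main model leaves out. With replicate number as a block, lactate against control gave 4244 genes, I-BET762 against control 206 and both treatments against I-BET762 973.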

Other observations

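The values here were chosen only after the result was seen, and no cause was tested. PLIN2 stood at 67.8, 67.7 and 63.4 CPM in control replicates 1, 3 and 4 and at 42.5 CPM in the library labelled control replicate 2. In I-BET762 replicates 1, 3 and 4 it stood at 38.2, 47.2 and 45.9 CPM and in the library labelled I-BET762 replicate 2 at 61.1 CPM. The interferon response, as a list mean relative to control, was -0.64, -0.21 and -0.12 in I-BET762 replicates 1, 3 and 4 and 0.15 in the library labelled I-BET762 replicate 2. Other genes followed the labels. SLC16A3 stood at 108.3 CPM in the library labelled control replicate 2 (other controls 80.7 to 133.4) and at 170.1 CPM in the library labelled I-BET762 replicate 2 (others 157.5 to 178.2), and ANGPTL4 at 10.4 CPM (7.6 to 12.7) and 15.2 CPM (14.0 to 21.6).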
